A study of Homo sapiens with 3 samples.

How the data were processed

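The samples were small extracellular vesicles (exosomes) shed into culture medium by human saphenous vein pericytes, the mural cells that sit around small vessels of the vein. There was 1 group of 3 samples, 1 per donor, and no control or treated group. Per the labels' protocols, cells at passage 6 were kept at 2% oxygen in endothelial growth medium with 2% serum depleted of exosomes, and medium was taken every 3 days. Cells and debris were removed by spins of 10 min at 300 g and 30 min at 16000 g, and vesicles were then isolated on Exo-spin columns. RNA was extracted with the miRNeasy chemistry, and 10 µl of a synthetic worm miRNA, cel-miR-39, at 5 fmol per µl was spiked in. Complementary DNA was made and amplified with SYBR Green on ready-made human miRNA PCR plates of the miRCURY system (panels 1 and 2), read on a QuantStudio 6 Flex, per the labels.

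The deposited values are raw quantification cycles (Ct), the PCR cycle at which a well's fluorescence crosses a threshold, with 1 value per assay and library and no normalisation by the authors, per the file headers. A lower Ct stands for more template. The deposited tables give the word Undetermined for a well without amplification. Threshold and baseline settings are not given in the sources used here. The authors also deposited a table of both panels together, whose header calls it normalised. Its values were those of the 2 panel tables: over 751 assays no cell was determined in 1 table alone, and the largest difference was 0.0005 cycles. It was therefore used only for this check. The value columns carry names that do not match the donors in the labels, so which column belongs to which donor is not settled, and the libraries are called A, B and C.

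Each library had 768 wells, 384 per panel. They held 751 human miRNA assays, 371 on panel 1 and 380 on panel 2, and 17 control wells, among them water blanks, small nuclear and nucleolar RNAs, spike-ins and the interplate calibrator UniSp3. Each assay had 1 well per library, so the error of repeat wells could be read only from UniSp3, with 6 wells per library. At a Ct of 18.3, UniSp3 does not give the error of wells near the limit of detection. With 1 library per donor, the SD over libraries cannot separate donor differences from technical error. The files hold no read counts, so depth is unknown, and the Ct itself sets the precision.

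A human miRNA counted as detected at a Ct under 37, a usual limit for these assays. Its level was the mean Ct of the miRNAs detected in all 3 libraries minus its own Ct, which is in log2 units if product doubles each cycle. Levels are given as mean ± SD over 3 libraries. Assays differ in efficiency, so the order of miRNAs is approximate. Agreement between libraries was taken across miRNAs as Pearson's r and Spearman's rho, without a p-value, since miRNAs are not independent replicates. With 1 group there was no comparison between groups, no pairing and no other split of the samples to test.

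Before the data were examined, 22 miRNA lists were fixed, covering cell types, hypoxia, angiogenesis, fibrosis, families, genomic clusters, miRNAs abundant in serum or blood, and usual reference assays. Names were matched to the panels, and 11 of the listed miRNAs had no human assay of that name, such as miR-210-5p, miR-378a-3p and miR-1246. The share of each list detected in all 3 libraries, and its median level with miRNAs not detected placed at the limit of detection, were set beside 10000 random lists of the same size drawn from the 751 assays. The percentile describes these libraries and is not a test across donors. The lists share members, so their percentiles are not independent. By chance, a nominal 1.1 of 22 lists would stand at or above the 95th percentile, a count made inexact by ties among random lists. The median level of the mesenchymal list minus that of each other cell type list was tested over libraries with a two-sided exact sign-flip permutation test, whose smallest p with 3 libraries is 0.25, or 0.5 where the difference is 0 in 1 library. For precursors with both arms assayed, the 5p arm was to be compared with the 3p arm where both were detected in all 3 libraries.

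The miRNAs named were also set by rule beforehand. They were the 25 with the highest level among those detected in all 3 libraries, the 5 most and 5 least variable, up to 4 of the highest members of each list, 9 miRNAs fixed by name (miR-132-3p, miR-210-3p, miR-126-3p, miR-21-5p, miR-143-3p, miR-145-5p, miR-451a, miR-122-5p and miR-223-3p), the 3 arm pairs with the largest difference in each direction, and the control assays. Any other miRNA named was chosen after its values were seen.

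Alternatives fixed beforehand were limits of detection of Ct 35 and Ct 40, each library left out in turn, detection in at least 2 libraries, other centrings (none, cel-miR-39, the calibrator subtracted, each panel on its own, the median, the reference assays), list means, detected members only, and a limit of 3 SD for arm pairs. Chosen after the data were seen were the removal of wells under Ct 29 and under Ct 25, and list detection in at least 1 library. Genomic neighbours were taken from RefSeq gene positions of GRCh38.p14, used only for which miRNA genes lie within 10 kb of each other, and 748 of the 751 assays matched a gene.

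The code was tested on simulated libraries of the 751 assays. All 60 planted miRNAs (100%) were recovered, levels correlated with the planted ones at r = 0.978 across miRNAs, and 3% of 200 null lists passed the 95th percentile. The planted miRNAs lay at cycles well before the limit of detection, so their recovery was nearly fixed in advance. Detection near the limit and early wells were not tested. The null lists were scored by mean level, not by the share detected or the median level used here. A simulated SD of 0.8 gave a median SD of 0.642 over 3 libraries, so a median of SDs over 3 libraries lies below the underlying SD. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.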

Results

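The miRNA content of vesicles released by human saphenous vein pericytes was profiled by quantitative PCR in 3 libraries, 1 from each of 3 donors. The stated purpose was the miRNA profile of these vesicles, so the design describes 1 group and holds no untreated or treated counterpart. Each library was read on 751 human miRNA assays. The spiked-in cel-miR-39-3p came up at a Ct of 16.1 ± 0.32 (SD, n = 3 libraries). The reverse transcription control UniSp6 came up at 17.3 ± 0.084, and the calibrator UniSp3 at 18.3 ± 0.10. Repeat wells of UniSp3 varied with an SD of 0.143, 0.117 and 0.0978 cycles in libraries A, B and C (6 wells each). None of the 6 water blanks gave a Ct. The small nucleolar RNAs SNORD38B and SNORD49A and the small nuclear RNA U6, all of which reside in the nucleus of cells, gave no Ct in any of 9 wells. No Ct was given either by UniSp2, UniSp4 and UniSp5 (0 of 9 wells), a set of RNA spike-ins of which no addition is stated in the labels.

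The first question was which miRNAs the vesicles carried. Few were detected, and most of those detected differed between libraries. A Ct under 37 was reached by 58 miRNAs in library A (7.72% of 751), 62 in library B (8.26%) and 136 in library C (18.1%). All 3 libraries shared 21 miRNAs (2.80%), another 38 were detected in 2 libraries and 117 in 1, and 575 in none. The 21 shared miRNAs exceeded what independent lists of these sizes would share, which is 0.867, and the highest of 10000 shuffles, which was 7. Of the miRNAs detected in library C, 79 (58.1%) were seen in no other library, against 17 (29.3%) for library A and 21 (33.9%) for library B. The number of shared miRNAs followed the limit chosen, with 12 under Ct 35 and 34 under Ct 40. It was 39 without library A, 39 without library B and 59 when detection in 2 libraries sufficed.

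Among the shared miRNAs, the highest levels after that of miR-27b-5p belonged to miR-100-5p, miR-21-5p and miR-125b-5p, which are abundant in fibroblasts and other mesenchymal cells. Their levels were 1.28 ± 0.65, 1.18 ± 0.63 and 1.14 ± 0.63 on the log2 scale (SD, n = 3), so that their order could not be told apart from the spread. They were followed by miR-1260a at 0.76 ± 0.73, the red cell miRNA miR-451a at 0.75 ± 1.20, miR-23a-3p at 0.51 ± 0.85, miR-221-3p at 0.46 ± 0.99 and miR-24-3p at 0.19 ± 0.85. Levels near or below the mean were found for let-7a-5p (0.0043 ± 1.79), miR-34a-3p (-0.52 ± 0.95), let-7b-5p (-0.52 ± 0.49), miR-19b-3p (-0.61 ± 1.46), miR-92a-3p (-1.39 ± 0.35), miR-31-5p (-1.41 ± 0.70) and miR-29a-3p (-1.60 ± 0.79). The lowest shared levels were those of miR-548c-5p (-2.18 ± 1.92), miR-188-3p (-2.18 ± 1.83), miR-663b (-2.52 ± 0.52), miR-27a-5p (-2.95 ± 2.35) and miR-144-3p (-2.96 ± 0.70). These levels moved when 1 library was left out, which also changed the miRNAs they were centred on. Without library C, miR-100-5p stood at 0.50, miR-125b-5p at 0.20 and miR-21-5p at 0.0063. Without library A, miR-21-5p stood at 2.22, and miR-23a-3p, at 1.72, passed miR-100-5p at 1.65 and miR-125b-5p at 1.59. Only these 21 met the rule that allowed 25 to be named.

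In first place by mean level stood miR-27b-5p, the minor arm of its precursor, at 12.57 ± 9.60. Its Ct was 32.9 in library A but 14.0 in library B and 14.2 in library C, earlier than the spike-in in both, so its rank rested on 2 wells. Its major arm, miR-27b-3p, had a Ct of 33.8 in library B and 33.3 in library C and no Ct in library A. Because every level is centred on the mean of the shared miRNAs, these 2 wells lowered the levels of the other miRNAs in libraries B and C. Without wells under Ct 29, 20 miRNAs were shared, miR-100-5p ranked first at 1.91 ± 0.21, and miR-125b-5p stood at 1.76 ± 0.38 and miR-21-5p at 1.81 ± 1.06. Leaving out library B kept 6 of the 10 highest miRNAs among the highest 10. Set against the spike-in, miR-100-5p came up 15.6 ± 1.3 cycles later, a 48490-fold lower signal if product doubles each cycle in both assays.

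**Figure D1:**
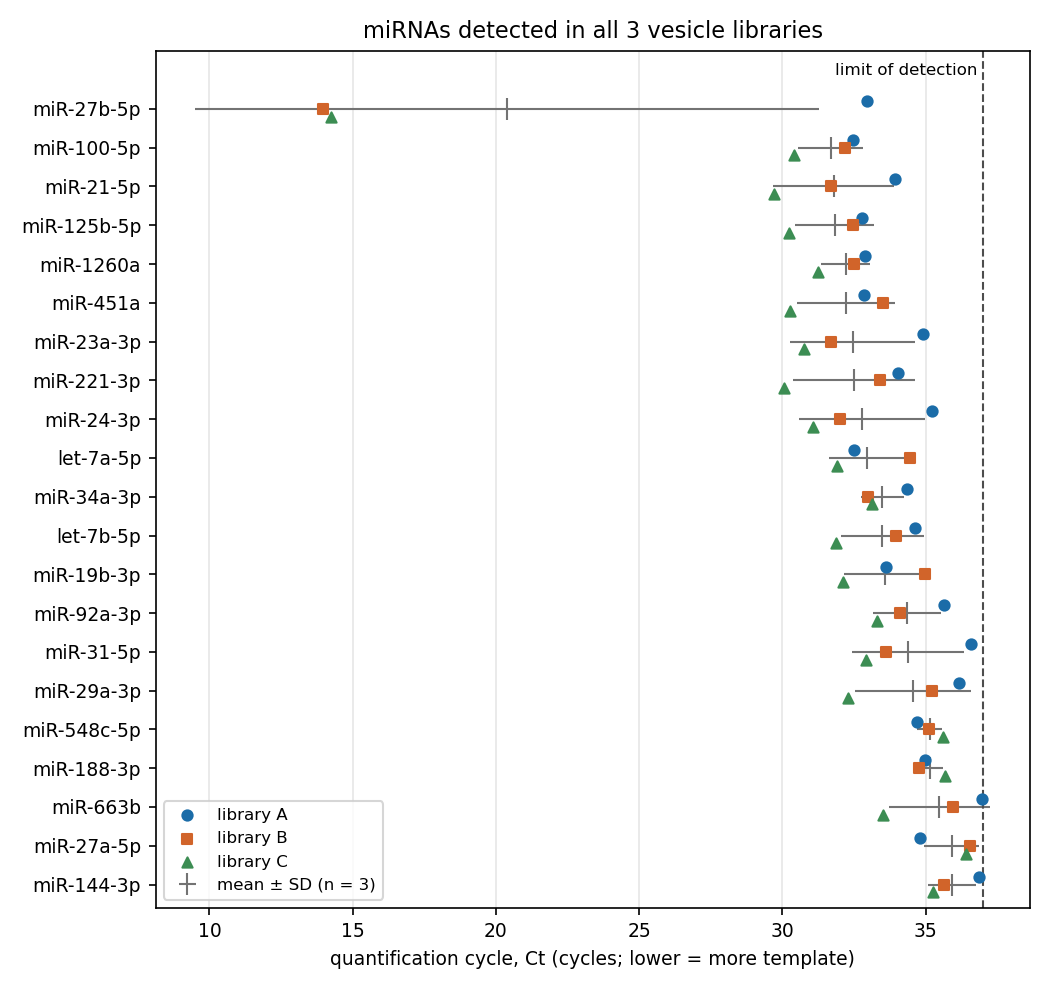
Quantification cycle (x axis, cycles, lower means more template) of the 21 miRNAs detected in all 3 libraries, ordered by mean level. Symbols are the 3 libraries, grey bars the mean ± SD (n = 3), and the dashed line the limit of Ct 37. Most values lie between Ct 30 and 37, and miR-27b-5p stands apart at 14.0 and 14.2 in libraries B and C against 32.9 in library A.

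The next question was how far the profile repeated over donors. Libraries B and C resembled each other most, with a Pearson r of 0.959 and a Spearman rho of 0.830 across the 21 shared miRNAs, which are not independent replicates. The r was 0.374 between libraries A and B and 0.453 between libraries A and C, with rho at 0.486 and 0.614. Without wells under Ct 29, and so without miR-27b-5p, r was 0.790 for B and C, 0.470 for A and B and 0.538 for A and C. The least variable miRNAs were miR-92a-3p, let-7b-5p, miR-663b, miR-21-5p and miR-125b-5p, with SDs from 0.35 to 0.63. The most variable were miR-27b-5p, miR-27a-5p, miR-548c-5p, miR-188-3p and let-7a-5p, with SDs from 1.79 to 9.60. These ranks depended on the centring. Without wells under Ct 29, miR-100-5p and miR-1260a had the smallest SDs, 0.21 and 0.26, while that of miR-21-5p was 1.06 and that of miR-663b 0.67. In Ct without centring, miR-548c-5p and miR-188-3p had the smallest SDs of all 21, 0.445 and 0.461 cycles, and miR-21-5p had 2.11. The median SD was 0.848, and 7 of 21 miRNAs had an SD over 1. Without centring, the median SD of the Ct was 1.42 cycles and 15 of 21 had an SD over 1, and on cel-miR-39 these were 1.64 and 17. The count over 1 was 11 with each panel centred on its own, 19 of 34 at a limit of Ct 40 and 21 of 39 without library B.

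Cycles were earliest in library C. Of the 21 shared miRNAs, 18 came up earlier in library C than in library A, with a median difference of -2.55 cycles. The 3 that did not were miR-548c-5p, miR-188-3p and miR-27a-5p. Library C was also earlier than library B for 17 of 21, with a median difference of -1.29 cycles, and library B earlier than library A for 16 of 21, with a median of -0.652. The spike-in cel-miR-39-3p in library C was 0.135 cycles later than in library A, but its Ct in library B minus library A was -0.472 cycles, in the direction of the miRNAs.

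The lists fixed in advance asked which cell types and processes the shared miRNAs belonged to. At or above the 95th percentile of random lists stood 11 of the 22 lists, against a nominal 1.1, and many lists share members. Random lists drew on all 751 assays, of which 575 were detected in no library. A list of commonly expressed miRNAs could pass for that reason alone, and both the pro-angiogenic and the anti-angiogenic list passed. A high percentile therefore does not single out a cell type or process. Of the mesenchymal and stromal list, 5 of 18 members were shared (percentile 99.995), namely miR-100-5p, miR-21-5p, miR-125b-5p, miR-31-5p and miR-29a-3p, and 14 of 18 were detected in at least 1 library. Of the mural and smooth muscle list, miR-24-3p and miR-221-3p were shared (2 of 10, percentile 98.4). The smooth muscle miRNAs miR-143-3p and miR-145-5p gave 1 Ct each, with a Ct of 37.3 for miR-143-3p, past the limit, and of 36.9 for miR-145-5p, both in library B. The percentile of the mural list fell to 91.9 at a limit of Ct 35, to 94.7 without library B and to 87.9 by detection in at least 1 library (4 of 10).

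Red cell and serum miRNAs were also present. Of the erythroid list, miR-451a and miR-144-3p were shared (2 of 6, percentile 99.4). The Ct of miR-144-3p lay near the limit, at 36.9, 35.6 and 35.3 in libraries A, B and C. At a limit of Ct 35, 1 of 6 was shared (percentile 95.1). The list of miRNAs abundant in serum or blood added miR-92a-3p (3 of 7, percentile 99.955), and its percentile was 94.3 at a limit of Ct 35. Other members were rarer: miR-16-5p had a Ct under 37 in libraries A and C, miR-122-5p, the liver miRNA, had a single Ct of 36.97 in library B, and miR-486-5p a single Ct of 36.96 in library B. The myeloid miRNA miR-223-3p gave no Ct in any library. No member of the leukocyte list (0 of 10) was shared, although miR-142-3p was detected in libraries A and C and 5 of 10 members in at least 1 library (percentile 96.5).

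Hypoxia and angiogenesis lists came next, the cells having been kept at 2% oxygen. Of 15 assayed hypoxia miRNAs, miR-21-5p, miR-23a-3p and miR-24-3p were shared (percentile 99.6), while miR-210-3p, the miRNA most closely tied to hypoxia, gave no Ct in any library. Of 15 pro-angiogenic miRNAs, miR-23a-3p, let-7b-5p and miR-31-5p were shared (percentile 99.6). The pro-angiogenic miR-132-3p was detected in library C alone, at a Ct of 34.2, as was miR-126-3p, the main endothelial miRNA, at 33.9. Of 18 anti-angiogenic miRNAs, miR-100-5p, miR-221-3p and miR-92a-3p were shared (percentile 99.3). The fibrosis and matrix list had miR-21-5p and miR-29a-3p in all libraries (2 of 12, percentile 97.7, and 90.3 at Ct 35).

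Families and genomic clusters differed. Of the miR-23/27/24 clusters, 4 of 11 members were shared (percentile 99.985), namely miR-27b-5p, miR-23a-3p, miR-24-3p and miR-27a-5p. Without wells under Ct 29, and so without miR-27b-5p, 3 of 11 were shared (percentile 99.86). The let-7 family had let-7a-5p and let-7b-5p (2 of 9, percentile 98.7), and the miR-17-92 cluster with its paralogs had miR-19b-3p and miR-92a-3p (2 of 15, percentile 96.5). The miR-17-92 percentile was 87.9 at Ct 35 and 91.3 at Ct 40, and that of let-7 was 90.9 when 2 libraries sufficed. None of the 54 assayed miRNAs of the imprinted DLK1-DIO3 cluster was shared, yet 24 were detected in at least 1 library (percentile 99.97), 18 of them in library C, among them miR-136-5p and miR-134-5p. The 24 included miR-411-5p, at a Ct of 15.7 in library A alone. Of the 45 miRNAs of the chromosome 19 cluster, whose expression is largely placental, 4 were detected in at least 1 library (percentile 0.615).

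No member of the remaining lists was shared. This held for the endothelial list (0 of 2), the hepatocyte list (0 of 6), the epithelial list (0 of 11), the neuronal list (0 of 11), the striated muscle list (0 of 7), the X-linked cluster from miR-506 to miR-514 (0 of 16), miR-371 to miR-373 (0 of 5) and the usual reference assays (0 of 7). Among reference assays 4 were detected in 2 libraries, namely miR-16-5p, miR-191-5p, miR-423-5p and miR-423-3p. The percentile of the reference list was therefore 99.95 when 2 libraries sufficed, 98.2 at Ct 40 and 99.7 without library B. Each of these values counts miR-191-5p, whose Ct of 26.6 in library A was far earlier than 38.7 in library B and 33.5 in library C. The percentile of the endothelial list was 97.1 without library C, which rested on miR-126-5p, at a Ct of 16.3 in library A and 35.8 in library B. By detection in at least 1 library, the percentile was 97.2 for the endothelial list (2 of 2) and 99.6 for the reference list (5 of 7).

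**Figure D2:**
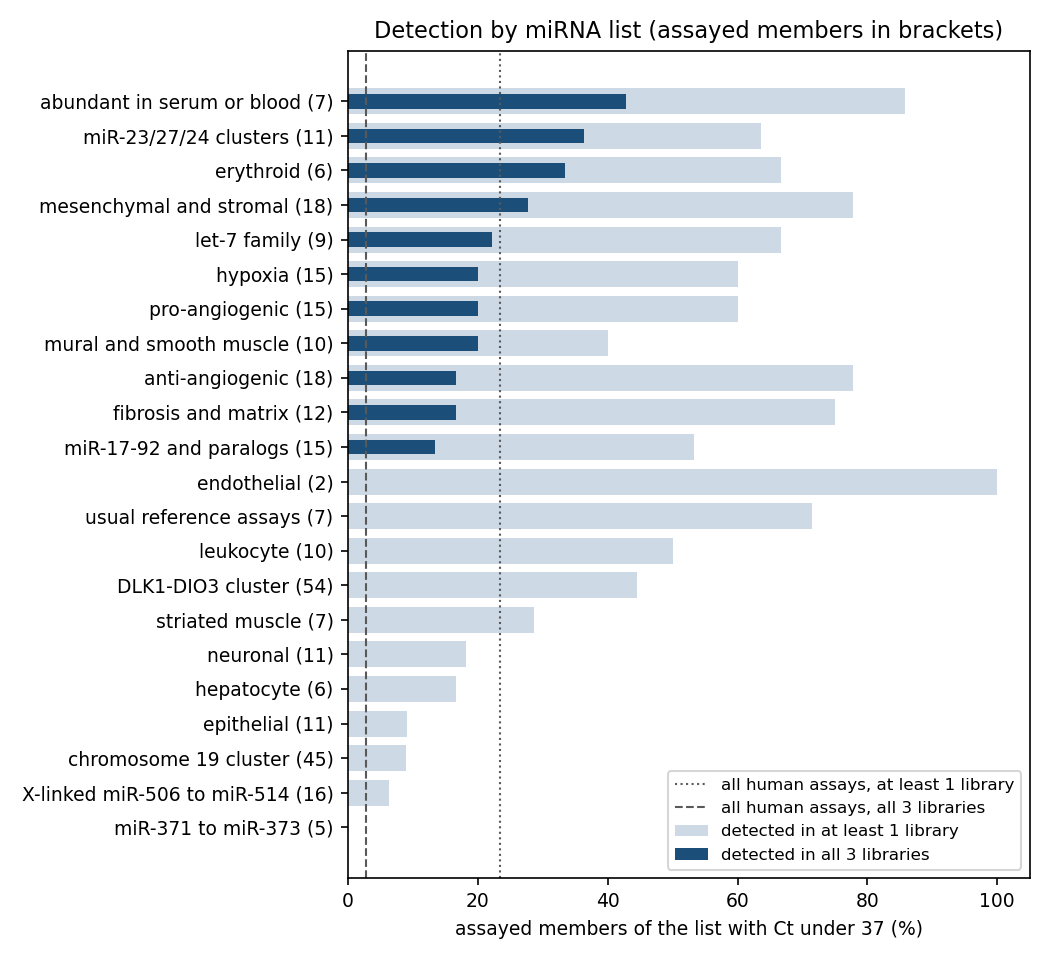
Percent of the assayed members of each list (x axis) with a Ct under 37, in all 3 libraries (dark bars) and in at least 1 library (light bars). Vertical lines give the same shares for all 751 human assays, 2.80% and 23.4%. Members of 11 lists were detected in all 3 libraries, led by the list abundant in serum or blood (42.9%), and none of the other 11.

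By median level with miRNAs not detected at the limit, 12 of 22 lists were at or above the 95th percentile, and 7 without library C. The highest medians were those of the endothelial list (0.13), whose 2 members include miR-126-5p at a Ct of 16.3 in library A, the miR-23/27/24 clusters (-2.18), the reference assays (-2.28), the hypoxia list (-2.81) and the mesenchymal list (-2.87). Taken over detected members only, 1 list was at or above the 95th percentile.

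By medians, the mesenchymal list differed from the other cell type lists by less than the spread between libraries. The medians of the mural, leukocyte, hepatocyte, epithelial, neuronal and striated muscle lists lay at the limit of detection in every library, so 1 value, the mesenchymal median above the limit, served for all 6, at 1.15 ± 1.83 (SD, n = 3). The difference from the erythroid list was 0.90 ± 1.40. In library A these differences were 0, as the mesenchymal median lay at the limit too, so the exact sign-flip test could give no p under 0.5 and decided nothing there. The difference from the serum or blood list was 0.52 ± 0.88 (two-sided exact sign-flip p = 0.5, smallest possible 0.25). At a limit of Ct 40 the difference from the serum or blood list was -0.98. Without library C, the difference of 1.15 fell to 0.097, that from the erythroid list to 0.087 and that from the serum or blood list to 0.015. Against the endothelial list it was -3.02 ± 6.44 (exact sign-flip p = 0.75), which rested on miR-126-5p at a Ct of 16.3 in library A, and it was 0.43 without wells under Ct 29 and 0.65 without library A. By list means, the mesenchymal list was higher in 3 of 3 libraries than each of 7 lists, by 0.71 ± 0.58 for mural, 0.81 ± 0.70 for erythroid, 1.34 ± 0.39 for neuronal, 1.48 ± 0.92 for leukocyte, 1.75 ± 1.01 for striated muscle, 1.78 ± 1.06 for epithelial and 1.87 ± 1.21 for hepatocyte miRNAs. The exact sign-flip p was 0.25 for each of these 7, the smallest that 3 libraries allow. In library C the neuronal mean included miR-7-5p, at a Ct of 22.2 there and without a Ct in libraries A and B. That well lowered the neuronal difference in library C, so 1.34 and its SD rest in part on it. List means without wells under Ct 29 were not examined. By means it was 0.23 ± 0.42 above the serum or blood list and at -2.30 ± 6.21 against the endothelial list (exact sign-flip p = 0.5 and 1).

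Arms of one precursor could not be compared. Both arms were assayed for 198 precursors, and for none were both detected in all 3 libraries. One arm was detected in all 3 for 14 precursors, the 5p arm for 8, such as miR-21 and miR-100, and the 3p arm for 6, such as miR-221 and miR-29a. For 8 of the 14 the other arm was detected in no library. At a limit of Ct 40, 1 pair could be compared, that of miR-23a, in which the level of the 5p arm minus that of the 3p arm was -4.47, -7.06 and -8.34 in libraries A, B and C.

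Some wells lay far outside this range. A Ct under 29, earlier than any well of miR-21-5p, was given by 25 wells of 21 assays, of which 6 were in library A, 5 in library B and 14 in library C. No assay had such a Ct in all 3 libraries, 4 had it in 2 and 17 in 1. The earliest, miR-187-5p at 12.5 in library C, had no Ct in either other library. These wells and miRNAs were chosen after their values were seen.

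**Figure D3:**
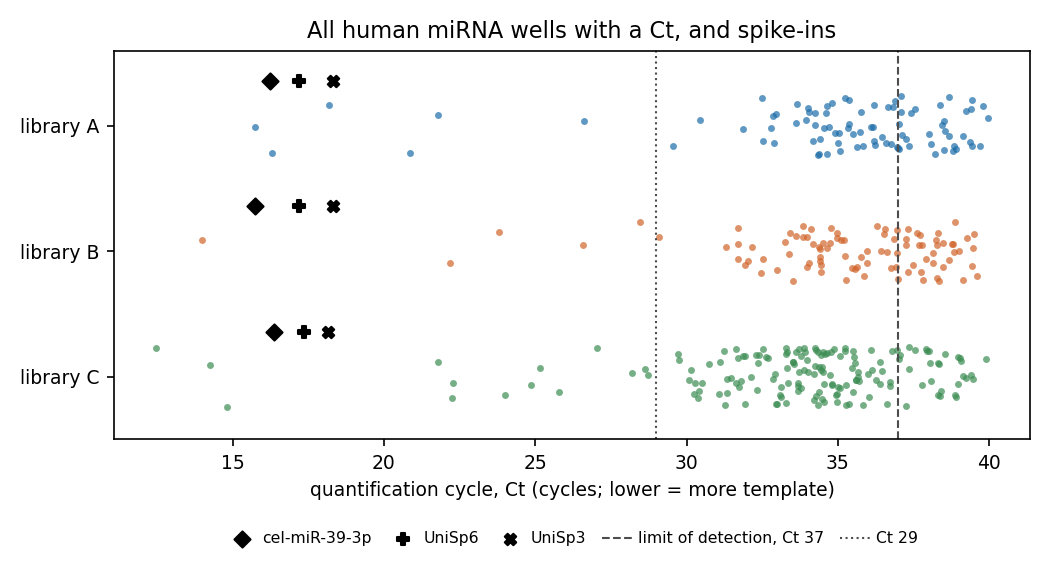
Quantification cycle (x axis, cycles) of every human miRNA well that gave one, by library. Points are single wells (89 in library A, 95 in library B and 165 in library C), black symbols the spike-ins and calibrator of the same library, the dashed line the limit of Ct 37 and the dotted line Ct 29. The bulk lies above Ct 29, and 25 wells lie below it, 5 of them earlier than cel-miR-39-3p.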

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

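All tests in this part were chosen after the results were seen.

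The assay for the mouse miRNA mmu-miR-378a-3p, which belongs to no comparison, gave a Ct of 34.8 in library C and none in the other libraries, with 1 well per library and no water control of this assay in the tables. Whether this assay also reads human miR-378a-3p was not examined, so the Ct is not shown to be an artifact.

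The 25 wells under Ct 29 fell in 21 assays. An abundant miRNA would be expected to give a Ct in the other libraries too. Of the wells of these assays that were not early themselves, 86.8% (33 of 38) were undetermined, which argues against abundance. This share leaves out the matching early wells of the 4 assays early in 2 libraries. Carry-over from an adjacent well is argued against as well, as 4% of the early wells touched an earlier well of the same plate and library. Early wells of both panels lay at the same plate position for 2 positions, B17 and D04, which 3.06% of 10000 random placements matched, so an effect of plate position may contribute and remains open for those positions. Independent events in each well would rarely repeat, yet 4 assays were early in 2 libraries, where 0.245 would be expected and the highest of 10000 shuffles gave 3, so the assay or its position may matter for these 4, which were miR-302c-3p and, at those 2 positions, miR-27b-5p, miR-589-5p and miR-890.

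Shared miRNAs came up earlier in library C than in library A (median difference -2.55 cycles). A more efficient reaction is argued against by the reverse transcription control UniSp6, whose Ct in library C minus library A was 0.151 cycles. The calibrator UniSp3, at -0.184 cycles, argues against it for the PCR. Better recovery in the RNA extraction is argued against by cel-miR-39-3p, at 0.135 cycles. The spike-in is described with the RNA extraction, so it does not report the yield of the earlier spins and columns. Among these 21 miRNAs, miR-27b-5p alone had wells under Ct 29. More vesicle RNA in library C, from more medium, more cells, a higher vesicle yield or the donor, may account for the difference. It remains open, because neither cell number nor vesicle yield is given in the sources used here. No biological explanation was tested, as the design names no group that separates library C from the others.

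Only some panel 2 miRNAs showed this difference. Of the shared miRNAs without early wells, all 14 of panel 1 were earlier in library C than in library A, with a median of -2.67 cycles, but 3 of the 6 of panel 2, with a median of -0.268 (SD 1.91), and the difference between panels was not tested. A smaller amount of library C on panel 2 remains open, since without early wells the ratio of miRNAs detected in library C to library A was 1.86 on panel 2 (26 to 14) and 2.53 on panel 1 (96 to 38), although with them it was 2.43 and 2.32. Signal that does not follow the input, such as primer products of miR-548c-5p, miR-188-3p and miR-27a-5p, could also give this pattern and cannot be told apart from it or from miRNA that differed less between donors, since the tables hold no water control for these assays and only 6 assays were compared.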

How the results depend on the processing

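Wells under Ct 29 or Ct 25 treated as not detected, and list detection in at least 1 library, were chosen after the data were seen. Of the alternative values of the main results, 127 stayed within the spread or within 1.5 times the count, and 18 did not. This tally is no measure of stability. It includes list contrasts, each judged by an SD larger than its difference, so that a change of sign could count as staying. The 10 highest miRNAs could not change without normalisation or on cel-miR-39. Removal of wells under Ct 29 gave the same main results as removal of wells under Ct 25, but not the same as with all wells kept. Under both, the median r was 0.538 against 0.453 with all wells, and the median SD 0.990 against 0.848. At a limit of Ct 35, 12 miRNAs were shared, the median SD was 1.07 and 7 lists were at or above the 95th percentile. At Ct 40 these were 34 miRNAs and a median SD of 1.22, 1 arm pair could be called, and the mesenchymal minus serum or blood difference was -0.98. The median SD was 1.42 without normalisation and 1.64 centred on cel-miR-39. Detection in 2 libraries gave 59 miRNAs, and list levels over detected members only put 1 list at or above the 95th percentile. Leaving out 1 library in turn gave 23 to 39 shared miRNAs, 0 to 3 arm pairs, a median r from 0.251 to 0.933, a median SD from 0.692 to 1.09, 6 to 9 of the 10 highest miRNAs and 7 to 10 lists by level. Higher counts under a looser limit or with fewer libraries follow from the rule itself. The cause of the other changes was not tested. The direction of the difference between the mesenchymal and endothelial lists also changed sign, to 0.43 without wells under Ct 29 and to 0.65 without library A. Treating wells under Ct 29 or 25 as not detected left 20 shared miRNAs and 11 lists at or above the 95th percentile. Of 241 alternative levels of shared miRNAs, 192 stayed within 1 SD and 49 did not. The 192 overstate stability. Without normalisation, centred on cel-miR-39 and with each panel on its own, the mean level over libraries could not change. The settings of Ct 29 and Ct 25 gave the same levels. Centring on the reference assays could not be run, since no reference assay was detected in all 3 libraries. No paired analysis was possible because there was 1 group. Most Ct values lay within a few cycles of the limit, where 1 well per assay decides detection, so a miRNA not detected in a library is not shown to be absent from it.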

Other observations

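The test of neighbouring miRNA genes was chosen before its result was seen, and that of blood or serum after. In the former, a first matching of assay names to genes found too few of them, so the test was void, and it was replaced with the prediction kept, although some of the neighbours had by then been seen.

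Library C detected 18.1% of all assays, against 7.72% in library A and 8.26% in library B, and more members of several lists. It detected 14 of the 18 mesenchymal miRNAs, 14 of 18 anti-angiogenic and 18 of 54 of the DLK1-DIO3 cluster, whereas library A detected 6, 5 and 5 of these lists and library B detected 9, 5 and 5. Other lists did not follow the total, with 4, 5 and 4 members of the serum or blood list in libraries A, B and C, 2, 4 and 3 of the mural list and 3, 0 and 2 of the chromosome 19 cluster. Among the miRNAs detected in libraries B and C but not in A were miR-199a-3p (Ct 34.4 and 31.6), miR-22-3p (33.3 and 31.7), miR-27b-3p, miR-27a-3p and miR-34a-5p, and miR-320a (34.0 and 31.3). In the DLK1-DIO3 cluster, miR-134-5p, miR-409-3p and miR-382-5p were detected in library C alone, at Ct 32.4, 32.8 and 33.1. These miRNAs were chosen after their values were seen.

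Shared miRNAs often came from neighbouring genes. One hypothesis is that they reached the vesicles in proportion to transcripts that hold several miRNAs, so that neighbours are detected together. Of the 20 shared miRNAs other than miR-27b-5p, 10 had another shared miRNA gene within 10 kb, against a median of 2 and a 95th percentile of 4 in 10000 random sets of the same size, of which 1 was as high. They were miR-23a-3p, miR-24-3p and miR-27a-5p, miR-92a-3p and miR-19b-3p, miR-144-3p and miR-451a, and let-7a-5p with let-7b-5p and miR-100-5p. Several of these have a second gene elsewhere, and neighbours are in part of one family, so the count may in part come from abundance of those families, which was not tested. Random sets drew on all 748 matched assays, and 575 of the 751 assays were detected in no library. Commonly expressed miRNAs could exceed such sets for that reason alone, so the count does not single out shared transcripts.

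A further hypothesis is that miR-451a and miR-144-3p came with serum or blood rather than from the pericytes, the medium having held 2% serum, which had been depleted of exosomes, a step meant to remove vesicles of the serum. Of the other 5 assayed miRNAs of the serum or blood list, 1 was detected in every library, miR-92a-3p, while miR-223-3p was detected in none, so carry-over of serum or blood RNA is neither shown nor excluded. Unconditioned medium taken through the same isolation, which is not analysed here, would test carry-over from the serum of the medium, but not from blood of the donor.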
